A study of Mus musculus with 2 samples.

How the data were processed

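CD8+ T cells were purified by negative selection, to a purity above 90% per the labels, from mice infected with Listeria monocytogenes expressing ovalbumin, at day 6 after infection. RNA of cells from Bcl11bF/F/dLck-iCre mice, in which Bcl11b is deleted in T cells, was compared with RNA of wild-type cells on 2 2-colour Agilent mouse arrays, 1 per biological replicate. Per the labels' protocols, RNA was linearly amplified and the dyes were attached chemically. Deficient RNA carried Cy5 and wild-type RNA Cy3 on both arrays, so a dye effect on a gene cannot be told from an effect of genotype. Both arrays lie on 1 slide and share the scanner settings, so neither slide nor scan could be tested as a batch.

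Per the file headers, the scanner files hold spot intensity values, the mean brightness of each spot and the median of its local background, made with Agilent Feature Extraction 9.5.3.1, which the submitters' processing notes also name. Per the file headers, the program also subtracted a fitted background surface, applied linear and LOWESS dye normalization and wrote a log10 ratio of red over green. The deposited value table holds that log10 ratio: its columns differ from the scanner files by at most 0.00500 on the log10 scale (replicate 1) and 0.00493 (replicate 2), and the median of each column is 0. Its direction is deficient over wild type, and no centring beyond the dye normalization was found.

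Each array has 45018 spots, of which 43379 belong to genes, 153 are negative controls and 1486 are positive controls. Of 41174 gene probes, 24375 were named through their accession and 8727 through a symbol or synonym in a RefSeq table of assembly GRCm38.p6, used for names alone, and 8072 kept the name on the array. Probe coordinates are those of the array files, on build NCBI36 (mm8). No genome of that build was used here, so exons were not assigned.

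Background was corrected with normexp (offset 50) on the mean signals minus the local background. Ratios were normalized by loess within each array, with control spots at weight 0, and not between arrays. Spots marked as non-uniform or population outliers were left out (255 and 195 gene spots), and duplicate spots of a probe were averaged. Probes were kept where 1 channel was well above background on both arrays, which left 12641 probes and 9949 genes. The probe with the highest mean intensity stood for its gene, and 38 called genes had another probe of opposite sign. Symbols that could not be named belonged to 16 higher and 102 lower genes. Of gene spots, 26.0% to 32.4% were well above background per channel and array, and 1 was saturated in 1 channel. The log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), and statmod 1.5.0 served the fit of separate channels. The 2 arrays leave 1 residual degree of freedom per gene. The estimated prior variance was 0.350 with infinite prior degrees of freedom, so every gene received the same standard error of 0.42 and the call amounted to a limit on the mean log2 ratio: the smallest absolute value called was 1.18. The number of arrays limits the precision.

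Gene lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over the 24 of 28 lists with at least 5 measured members; camera with an estimated correlation and fry were run beside it. The tests, the lists and the rule for named genes were fixed before the data were examined. The rule names Bcl11b, then the 15 higher and 15 lower genes with the largest absolute mean log2 ratio among those that passed with the same sign on both arrays, without clone, predicted-gene or accession names, and up to 4 members of each list with the smallest adjusted p. A gene not well above background in 1 group on both arrays has only a bound there: the mean of the brighter group over the mean of, per array, the higher of the lowest signal well above background and the probe's own, per channel after loess and Aquantile. Such bounds remain open to dye bias.

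The procedure was tested on simulated data for this comparison, with 9949 genes of which 200 were changed, in 20 draws. It recovered 15.3% of genes changed by 1 on the log2 scale, 92.4% of those changed by 2 and 100% of those changed by 3, and 4.14% of calls were false. Noise in those draws had the fitted prior variance of 0.350 for every gene, as the test assumes. The arrays differed in the SD of their ratios (0.96 and 0.65) and shared the dye orientation. So 4.14% is not the false share among the calls on the arrays. In those draws, which carry no correlation between genes, camera called 1 unchanged list over all draws and called a list shifted by 1 in 20 of 20 draws.

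Alternatives were the Feature Extraction ratios, no background correction, a normexp offset of 16, median centring, Aquantile normalization, the deposited value table, no filter on dim probes, a filter on both channels, the mean of a gene's probes, single probes, an intensity trend with a robust prior, a test against a 1.2-fold change, separate channels, and each replicate alone. Chosen after seeing the data were the fitted background surface under normexp, centring each array on its genes' median, and natural killer lists without genes that myeloid cells share.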

Results

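Gene expression was compared between Bcl11b-deficient and wild-type CD8+ T cells taken from mice at day 6 of a Listeria infection. Bcl11b is a zinc-finger transcription factor of T cells, and dLck-iCre deletes floxed alleles in T cells. The data are 2 arrays, each with deficient RNA in one colour and wild-type RNA in the other from 1 biological replicate. Wild-type RNA was well above background at 32.4% of gene spots on replicate 1 and 28.9% on replicate 2, and deficient RNA at 26.0% and 31.1%. Negative control spots had median intensities of 326.5 and 406 in the wild-type channel and 968 and 707 in the deficient channel, against a local background of 37 and 47. Dim spots therefore carry a background that the local measurement misses. All ratios below are deficient over wild type, as the mean of 2 arrays with the SD (n = 2), and adjusted p-values are from limma unless a list test is named.

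Bcl11b itself was lower in deficient cells. Its brighter probe (NM_021399, chromosome 12, 108363444 to 108363503, build NCBI36) had a log2 ratio of -1.82 ± 1.60 (SD, n = 2), with -0.69 on replicate 1 and -2.95 on replicate 2 (limma adjusted p = 6.6e-04). The second probe (NM_001079883, 108358529 to 108358588) gave -1.09 and -2.03, and the deficient channel was not well above background for it on either array. T-cell receptor and CD8 signalling genes had a median of -0.76 on each array. The brighter probe thus fell no further than that median on replicate 1, and further on replicate 2. Whether Bcl11b fell beyond other T-cell genes was not tested. The labels do not say which part of the gene was deleted, and a probe outside that part does not test the deletion. Over 15 alternatives the ratio stayed below 0 and passed in 10, with an adjusted p from 1.29e-05 to 0.271; it did not pass with the Feature Extraction ratios (adjusted p = 0.134) or without background correction (adjusted p = 0.0670).

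Across the genes tested, macrophage genes led the higher side, and T-cell receptor components were among the lower genes. Of 9949 genes, 363 were higher and 591 were lower in deficient cells, and 361 and 579 of these had the same sign on both arrays. Beyond 2-fold on both arrays were 257 genes upward and 186 downward. Because the fit gave every gene the same error, these counts are those of genes beyond 1.18 on the log2 scale, and they moved widely: 56 and 76 genes with the Feature Extraction ratios, 231 and 162 with the fitted background surface, and 0 and 0 with separate channels in limma (1996 genes at an unadjusted p under 0.05) or without a filter on dim probes (5116 genes). Lower genes made up 61.9% of the calls after loess, 83.5% with median centring, 38.8% without background correction and 51.2% with each array centred on its genes' median, which was -0.22 on replicate 1 and -0.01 on replicate 2. That centring adds 0.11 to every mean log2 ratio given here, and puts Bcl11b at -1.71. Median centring in place of loess moved the genes' median to -0.75 on replicate 1 and -0.07 on replicate 2. Called genes followed across the 14 or 15 alternatives passed in at least 10 unless a tally is given, and genes chosen after their values were seen were not followed. These tallies do not count independent checks. The deposited value table repeats the Feature Extraction ratios, and Aquantile keeps the log2 ratio of each probe. On single arrays, replicate 1 had 755 genes above 2-fold and 2146 below, and replicate 2 had 638 and 250.

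**Figure D1:**
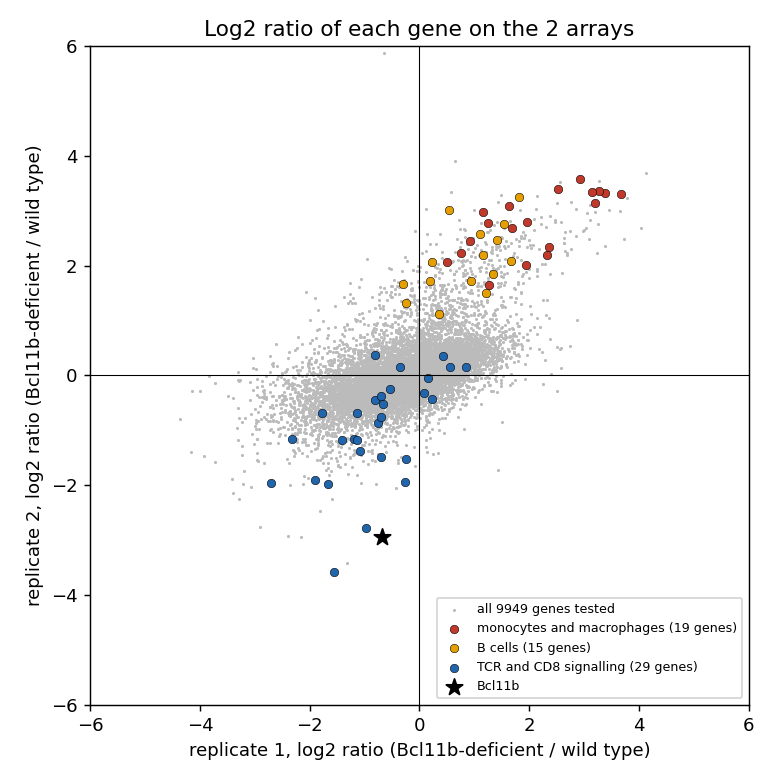
Log2 ratio (deficient over wild type) of each of 9949 genes on replicate 1 (x axis) and replicate 2 (y axis), with 3 gene lists and Bcl11b marked. All 19 macrophage markers lie above 0 on both arrays, and 21 of 29 T-cell receptor and CD8 signalling genes lie below 0 on both.

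The 2 arrays ranked genes alike in part. Their log2 ratios correlated across genes at Pearson r = 0.593 and Spearman rho = 0.612, where genes are not independent replicates and both arrays share the dye orientation, and 74.0% of genes had the same sign. The SD of the ratios across genes was 0.96 on replicate 1 and 0.65 on replicate 2.

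Genes of monocytes and macrophages were the highest group. All 19 measured members rose, over all genes and adjusted over the list alone, with a median log2 ratio of 2.35 (1.96 on replicate 1 and 2.80 on replicate 2; camera adjusted p = 1.46e-44, and adjusted p = 0.585 with an estimated correlation). Apoe, an apolipoprotein that macrophages secrete, rose most (3.91 ± 0.30, SD, n = 2; chromosome 7, 18854905 to 18854964). C1qc, a chain of complement C1q, rose by 3.49 ± 0.26, Adgre1, which encodes the macrophage antigen F4/80, by 3.35 ± 0.04, and Csf1r, the receptor for macrophage colony-stimulating factor, by 3.25 ± 0.46. Vcam1 (3.32 ± 0.07), the haem oxygenase Hmox1 (3.25 ± 0.15) and Cd5l (3.17 ± 0.04), a secreted protein of tissue macrophages, rose too. Among the 15 genes with the largest rise were also the protease inhibitor Slpi (3.51 ± 0.39), the Fc receptor gamma chain Fcer1g (3.41 ± 0.20), properdin Cfp (3.36 ± 0.95), Rab7b (3.33 ± 0.46), cathepsin B Ctsb (3.24 ± 0.30), Lst1 (3.11 ± 0.87), Plbd1 (8.59-fold) and Igf1 (3.09 ± 0.16). Their adjusted p-values ran from 1.1e-16 for Apoe to 1.07e-10 for Igf1. The lowest values over the alternatives were 2.08 for Vcam1 and 1.81 for Ctsb. No call on these genes was made with separate channels or without the filter on dim probes.

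Markers of other cell types that a CD8+ preparation can hold were also higher. Of 15 B-cell markers 10 rose (12 adjusted over the list alone; median 1.59, camera adjusted p = 1.97e-14, and adjusted p = 0.763 with an estimated correlation), among them the class II gene H2-Ab1 (2.53 ± 1.02) and Ms4a1, which encodes CD20 (1.94 ± 0.74). Of 10 neutrophil markers 4 rose (8 over the list alone; median 1.12, camera adjusted p = 3.97e-11, and adjusted p = 0.585 with an estimated correlation), with S100a9 at 2.79 ± 0.43 and Chil3, which macrophages also express, at 3.05 ± 0.69, beside S100a8 (2.46 ± 0.32) and Camp (1.70 ± 0.21). Of 7 dendritic cell markers 4 rose (4 higher and 1 lower over the list alone; median 1.72, with 1.05 on replicate 1 and 2.38 on replicate 2, camera adjusted p = 0.00131, and adjusted p = 0.763 with an estimated correlation), namely Itgax (2.00 ± 1.09), Cd83 (2.00 ± 0.70), Irf8 (2.04 ± 0.54), which B cells express too, and Batf3 (1.72 ± 0.94). Of 10 erythroid markers 4 rose (6 over the list alone; median 1.03, with 0.44 on replicate 1 and 1.69 on replicate 2, camera adjusted p = 2.53e-06, and adjusted p = 0.763 with an estimated correlation), among them the globin genes Hbb-bt (2.06 ± 0.98) and Hba-a1 (1.39 ± 0.86), each of which has near-identical copies that its probe cannot be assumed to separate, beside Alas2 (1.40 ± 0.99) and Slc4a1 (1.48 ± 1.55). Of 6 plasma cell markers Jchain rose (2.00 ± 1.42) and Txndc5 fell (-1.26 ± 1.44), with 3 higher and 1 lower over the list alone (median 0.87, with 0.76 on replicate 1 and 0.54 on replicate 2, camera adjusted p = 0.0275, and adjusted p = 0.763 with an estimated correlation). Lists with under 5 measured members were not tested: platelets had a median of 0.29 over 4 genes with Clec1b higher (1.69 ± 0.28), stroma 0.64 over 3 genes with Vwf higher (1.59 ± 0.08), and CD4 T cells 0.19 over 2 genes, of which limma called 0 (0 also at an unadjusted p under 0.05). No gamma-delta T-cell marker was measured. The lowest values over the alternatives were 1.54 for H2-Ab1, 1.09 for Ms4a1, 1.81 for S100a9, 1.30 for Cd83, 1.17 for Irf8, 1.07 for Batf3 and 1.14 for Jchain. They were 0.99 for Hbb-bt, 0.36 for Hba-a1, 0.61 for Alas2, 0.59 for Slc4a1 and 1.02 for Vwf, and the last 4 of these passed in 8, 7, 8 and 9 of 15 alternatives. Txndc5 ran from -2.38 to -0.59 and passed in 4 of 14. Camp and Clec1b, well above background in wild-type cells on 1 of 2 arrays, ran from 1.17 to 2.57 and from 1.15 to 2.69, and Camp passed in 9 of 14.

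Part of the natural killer cell genes were higher as well. Of 12 receptors and adaptors 6 rose and Klra7 fell (-1.18 ± 0.59, well above background in deficient cells on 1 of 2 arrays; chosen after its value was seen), with 8 and 1 adjusted over the list alone (median 1.18, with 0.71 on replicate 1 and 1.51 on replicate 2, camera adjusted p = 7.6e-08, and adjusted p = 0.585 with an estimated correlation). Of 8 NK-cell markers 4 rose, also over the list alone (median 1.05, camera adjusted p = 3.62e-08, and adjusted p = 0.585 with an estimated correlation), and this was the list that fry called (adjusted p = 0.0141). The leading members Fcer1g, Tyrobp (2.82 ± 0.25) and Fcgr3 (1.59 ± 1.27) are shared with myeloid cells, whose markers rose in the same samples. Klrb1c, which encodes NK1.1, rose by 2.38 ± 1.28, Cd7 by 1.30 ± 0.74 and Klrk1, the receptor NKG2D, by 1.30 ± 0.72 (chosen after its value was seen). Among members that did not pass, Prf1 (-0.64 ± 0.39), Klrd1 (-0.28 ± 0.46) and Hcst (-0.26 ± 0.85) lay below 0. Eomes stood at 0.81 ± 0.25. Ncr1 was not well above background in wild-type cells, and deficient cells had at least 1.52-fold more. These members too were chosen after their values were seen. Fcgr3 and Klrb1c, well above background in wild-type cells on 1 of 2 arrays, ran from 1.14 to 2.54 and from 1.72 to 3.53 over the alternatives. Fcgr3 passed in 8 of 14, and Cd7 was 0.40 at the lowest and passed in 8 of 15. Of the 8 NK-cell markers, 7 stand in another list as well. Klra7 has near-identical paralogs and its assignment is uncertain. The genes set aside as shared went beyond the 3 leading members named above in the receptor list, which kept 8 of 12. Without them, 3 of 8 receptors were higher and 1 lower (median 0.97, camera adjusted p = 0.00336, and adjusted p = 0.763 with an estimated correlation). Of 6 NK-cell markers left, 2 were higher (median 0.78, camera adjusted p = 0.00337, and adjusted p = 0.763 with an estimated correlation).

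T-cell receptor and CD8 signalling genes were lower in deficient cells. Of 29 measured members 9 fell and limma called 0 higher (0 also at an unadjusted p under 0.05), with 13 lower over the list alone (median -0.88, camera adjusted p = 1.45e-06, and adjusted p = 0.585 with an estimated correlation). Cd6, a T-cell surface receptor, fell to -2.56 ± 1.44, Cd3e, a CD3 chain of the receptor complex, to -2.34 ± 0.53, Plcg1, the phospholipase that the receptor activates, to -1.91 ± 0.01, and Cd5 to -1.88 ± 1.29. Cd3e and Plcg1, well above background in deficient cells on 1 of 2 arrays, ran from -3.90 to -1.48 and from -3.24 to -1.20 over 14 alternatives. The SD of Plcg1 therefore understates its uncertainty. A probe for the receptor alpha chain, Tcra, gave the lowest ratio of the named genes measured in both groups (-2.84 ± 0.10, adjusted p = 4.79e-09; chromosome 14, 53158559 to 53158618), and was nearest to 0 at -1.73 over 15 alternatives. Other members lay near 0, such as Cd2 (-0.09 ± 0.47) and Zap70 (-0.12 ± 0.28), and Cd8a (-0.91 ± 0.33) and Cd8b1 (-1.10 ± 0.56) did not pass; these 4 were chosen after their values were seen. Cd28 and Fyn, chosen likewise, were not well above background in deficient cells, and wild-type cells had at least 1.66-fold and 1.30-fold more. Macrophage markers, at a median of 2.35, were higher in the same samples.

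Of 13 cytotoxic effector genes 2 rose and 3 fell (3 and 3 over the list alone; median -0.23, camera adjusted p = 0.775). Granzyme B, Gzmb, fell (adjusted p = 3.65e-08; chromosome 14, 55213150 to 55213209). Its deficient channel was not well above background on either array, so only a bound is measured, at least 2.98-fold more in wild-type cells. Cst7, an inhibitor of granule cathepsins, fell to -1.55 ± 0.15 (well above background in deficient cells on 1 of 2 arrays), and Crtam to -1.22 ± 0.49 (chosen after its value was seen), while Serpinb6b (1.86 ± 0.25) and the lysosomal protein Lamp1 (1.44 ± 0.11) rose. Of 9 effector cytokines and chemokines the chemokine Ccl5 rose (1.67 ± 0.38; 1 over the list alone), and Ifng, well above background in deficient cells on 1 of 2 arrays, stood at -0.60 ± 1.48 with opposite signs (median 0.15, camera adjusted p = 0.337). Nearest to 0 over the alternatives were -0.99 for Cst7, 1.00 for Serpinb6b, 0.66 for Lamp1 and 0.64 for Ccl5. Whether the risen genes rose within T cells was not tested, and macrophage (median 2.35) and B-cell markers (median 1.59) were higher in the same samples.

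Naive and memory-precursor markers were lower. Of 21 members 4 fell, also over the list alone (median -0.63, camera adjusted p = 0.00299, and adjusted p = 0.696 with an estimated correlation): Dapl1 (-2.36 ± 1.49), the transcription factor Lef1 (-1.55 ± 0.34), the integrin Itga6 (-1.48 ± 0.52) and Slamf6 (-1.47 ± 1.45). Itga6 and Slamf6, well above background in deficient cells on 1 of 2 arrays, ran from -2.66 to -0.90 and from -2.19 to -0.76 over 14 alternatives. Slamf6 passed in 8 of these, and Lef1 was -2.41 at the lowest of 15. Macrophage (median 2.35) and B-cell markers (median 1.59) were higher in the same samples. Of 25 effector and memory transcription factors 2 rose, Irf8 and Batf3, which the dendritic cell list also holds. Those that fell were 3, Tox, Lef1 and the chromatin organizer Satb1 (-1.55 ± 0.43, chosen after its value was seen), with the same counts over the list alone. Tox was not well above background in deficient cells, and wild-type cells had at least 1.65-fold more. That list's median was -0.22 while camera ranked it upward (adjusted p = 0.871). Of 26 effector differentiation and homing receptors 4 rose and 1 fell (4 and 2 over the list alone; median 0.28, with 0.03 on replicate 1 and 0.49 on replicate 2, camera adjusted p = 0.0441, and adjusted p = 0.763 with an estimated correlation). They included the galectin Lgals3 (2.22 ± 0.21), which macrophages also express, Cd44 (1.66 ± 0.38), Anxa1 (1.35 ± 1.73; passed in 6 of 15 alternatives), S100a6 (1.21 ± 0.26, chosen after its value was seen) and, downward, Cxcr6 (-1.48 ± 0.48). Over the alternatives Lgals3 was 1.40 and Cd44 0.97 at the lowest, and Cxcr6 -2.26. That list passed in 5 of 14 alternatives (adjusted p from 0.0188 to 0.935), and its median was -0.25 with median centring. Of 8 inhibitory and costimulatory receptors Havcr2 rose (0.12 on replicate 1 and 2.28 on replicate 2; passed in 4 of 15 alternatives), and Cd96 (-1.35 ± 0.34, well above background in deficient cells on 1 of 2 arrays) and Nt5e fell, as over the list alone (median 0.56, mean -0.10, camera adjusted p = 0.985). Cd96 ran from -2.12 to -0.78 and passed in 6 of 14 alternatives. Nt5e, the ecto-nucleotidase CD73, was not well above background in deficient cells, and wild-type cells had at least 2.09-fold more.

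**Figure D2:**
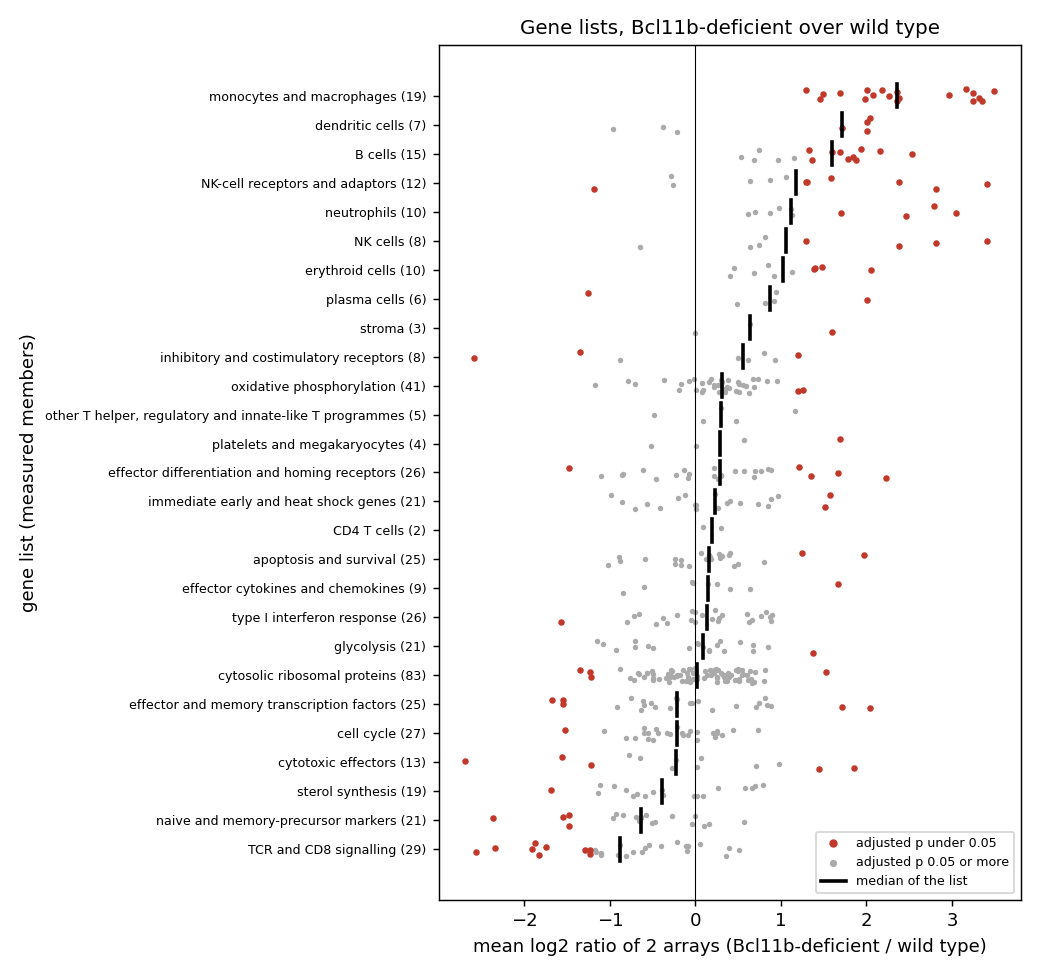
Mean log2 ratio of 2 arrays (deficient over wild type, x axis) of the measured members of each gene list (y axis, member counts in brackets), in red where the adjusted p is under 0.05, with the list's median as a black bar. Medians run from -0.88 for T-cell receptor and CD8 signalling to 2.35 for monocytes and macrophages.

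Other lower genes that the rule names were Rgcc (-2.56 ± 0.56) and, well above background in deficient cells on 1 of 2 arrays, Ddx18 (-2.78 ± 1.96), Usp28 (-2.76 ± 0.89), Fbxl12 (-2.57 ± 2.53) and Cep97 (-2.47 ± 1.02). Nearest to 0 over 14 alternatives these 4 were -1.40, -1.62, -1.22 and -1.41, and Cep97 was -3.77 at the lowest. For Rflnb, Gdpd3, Ift80, Eldr and the pseudokinase Trib2 the deficient channel was not well above background on either array, and wild-type cells had at least 2.12-fold, 3.15-fold, 3.42-fold, 3.54-fold and 3.44-fold more. These bounds give no order against the measured ratios, although the rule ranked fitted ratios. The deficient channel was likewise not well above background for 181 of the 591 lower genes (30.6%), whereas 13 of the 363 higher genes (3.58%) were not well above background in wild-type cells. Lower genes were dimmer, with a median log2 intensity of 9.28 against 10.82 for higher genes.

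Among metabolic and growth lists, oxidative phosphorylation genes were slightly higher. Of 41 members 2 rose (0 over the list alone), with 4 higher and 1 lower at an unadjusted p under 0.05 in limma. Their median was 0.31 (0.47 on replicate 1 and 0.16 on replicate 2, camera adjusted p = 0.0113, and adjusted p = 0.781 with an estimated correlation). Macrophage (median 2.35) and B-cell markers (median 1.59) were higher in the same samples. Cox7a2 (1.26 ± 1.08) passed in 6 of 15 alternatives, with 0.48 at the lowest, and Uqcrb (2.29-fold) in 4 of 15. Median centring put that list's median at -0.43, which is -0.02 relative to all genes, and it passed in 12 of 14 alternatives (adjusted p from 0.00137 to 0.713). Of 83 cytosolic ribosomal protein genes 1 rose and 3 fell (1 and 0 over the list alone, with 4 lower at an unadjusted p under 0.05; median 0.02, camera adjusted p = 0.324). They were Rpl37a (1.52 ± 1.22), Rpsa (-1.35 ± 0.83), Rpl29 (-1.23 ± 0.82) and Rpl4 (-1.22 ± 1.51), whose probes can also bind transcripts of near-identical pseudogenes. They passed in 7, 9, 6 and 6 of 15 alternatives. Rpl37a was 0.43 at the lowest, Rpsa -2.30 and Rpl4 -2.08, and Rpl29 ran from -2.19 to -0.80. Median centring put that list at -0.90, or -0.49 relative to all genes (adjusted p = 4.02e-07, with a range up to 0.938 over 14 alternatives). Of 27 cell cycle genes Ccne1, which encodes cyclin E1, fell, also over the list alone (-1.53 ± 0.61, well above background in deficient cells on 1 of 2 arrays; list median -0.22, camera adjusted p = 0.415). Ccne1 was -0.93 nearest to 0 and passed in 9 of 14 alternatives. Of 19 sterol synthesis genes the epoxidase Sqle fell (3 lower over the list alone; list median -0.39, camera adjusted p = 0.327). It was not well above background in deficient cells, and wild-type cells had at least 1.59-fold more; it passed in 8 of 14. Of 21 glycolysis genes Pfkfb3 rose, also over the list alone (1.38 ± 0.78; list median 0.08 and mean -0.01, camera adjusted p = 0.699). It was 0.75 at the lowest and passed in 8 of 15 alternatives. Of 25 apoptosis and survival genes Bcl2a1b (1.97 ± 0.28), which has near-identical paralogs, and Pmaip1 (1.24 ± 0.87; passed in 6 of 15 alternatives) rose, also over the list alone (list median 0.16, camera adjusted p = 0.264). Bcl2a1b was 1.21 at the lowest. Of 26 type I interferon response genes Sp100 fell, also over the list alone (-1.57 ± 0.49; list median 0.14, camera adjusted p = 0.327). It passed in 9 of 15 alternatives, from -2.05 to -0.18. It did not pass with the Feature Extraction ratios (-0.33). Of 21 immediate early and heat shock genes Gadd45b (1.52 ± 0.12) and Hspa1a (1.57 ± 2.06, with 0.11 and 3.03 on the arrays) rose, also over the list alone (list median 0.23, camera adjusted p = 0.126). They were 0.83 and 0.78 at the lowest, and passed in 9 and 8 of 15 alternatives. Of 5 helper, regulatory and innate-like T-cell genes limma called 0 (1 higher over the list alone and at an unadjusted p under 0.05; list median 0.30, camera adjusted p = 0.324).

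In all, 10 lists rose and 2 fell by camera at the preset correlation. With an estimated correlation, which rests on 1 residual degree of freedom, camera called 0 of the 24 lists (0 also at an unadjusted p under 0.05), and fry called 1 (3 at an unadjusted p under 0.05).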

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

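The test of these probes was chosen after the arrays were inspected. The arrays carry 10 control probes against adenovirus E1A transcripts, each on 32 spots, which the comparison of genotypes does not use. In both channels of both arrays, 7 of the 10 had a median signal above the 95th percentile of the negative control spots. Their brightest medians were 1902 in the deficient channel and 632 in the wild-type channel of replicate 1, and 1363 and 725 on replicate 2. Negative control spots had medians of 968 and 326.5 on replicate 1, and 707 and 406 on replicate 2. These signals therefore lie near the background that the local measurement misses. Over all 10 probes, including those not above that percentile, log2 ratios of deficient over wild type ran from -0.16 to 1.19 on replicate 1 (median 0.53) and from -0.41 to 0.52 on replicate 2 (median 0.05). The labels used here do not mention control RNA, and no explanation was tested.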

How the results depend on the processing

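The fitted background surface, centring on the genes' median and the natural killer lists without shared genes were chosen after seeing the data. Of the 85 called genes named besides Bcl11b, those measured lay on the same side of 0 in each of the 15 tested alternatives, but 34 kept their call with the Feature Extraction ratios, and 0 without a filter on dim probes or with separate channels in limma (5116 and 1996 genes at an unadjusted p under 0.05). Several alternatives had little room to turn a sign: Aquantile, the intensity trend, separate channels, the 1.2-fold test and changed filters reuse each probe's log2 ratio. Centring on the genes' median adds 0.11, against at least 1.18 in absolute value for a called gene. Of genes higher and lower, 56 and 76 passed both with the Feature Extraction ratios and with the deposited value table, 69 and 350 with median centring, 0 and 0 without the filter, where 27595 genes were tested, 0 and 0 with separate channels, 555 and 223 with both channels above background, and 231 and 162 with the background surface. Without background correction 183 were lower, and in the test against a 1.2-fold change 268. With 1 array left there is no test, and counts beyond 2-fold ran from 638 to 755 upward and from 250 to 2146 downward, the first of each pair without replicate 1; Bcl11b ran from -2.95 to -0.69. Bcl11b stayed below 0 but did not pass with the Feature Extraction ratios (-2.17), the value table (-2.18), no background correction (-1.52), no filter (-1.82, adjusted p = 0.271) and separate channels (-1.82, adjusted p = 0.228). The number of lists past the threshold by camera at the preset correlation stayed within 1.5 times of the 12 given, against 0 with an estimated correlation and 1 by fry, and the correlation of the arrays within 0.1. Of the 12 lists past the threshold, dendritic cells passed in 12 of 14 alternatives (adjusted p from 5.92e-04 to 0.0818), plasma cells in 11 of 13 (from 0.00720 to 0.168), oxidative phosphorylation in 12 of 14 and effector differentiation in 5 of 14, and the other lists in each one run.

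Among the called genes named, the only called genes followed across alternatives, none changed direction, for which several alternatives left little room. For lists, direction means that of camera, which can turn while the median keeps its sign, and medians are given. Cytotoxic effectors turned without background correction (-0.13), without the filter (0.16), with both channels above background (0.015), with an intensity trend (-0.23) and with separate channels (-0.23). Transcription factors turned without background correction (-0.11), with median centring (-0.59), no filter (-0.050), both channels (-0.22), the mean of probes (-0.32), single probes (-0.31) and separate channels (-0.22). Ribosomal proteins turned with the Feature Extraction ratios (-0.17), the value table (-0.17), median centring (-0.90), no filter (0.019) and both channels (0.019). Inhibitory receptors turned with an offset of 16 (0.57) and no filter (-0.044), sterol synthesis with both channels (0.18), and glycolysis (-0.54) and oxidative phosphorylation (-0.43) with median centring. Of single genes not called, Pecam1 turned with the Feature Extraction ratios (0.048), the value table (0.048), an offset of 16 (0.0040), median centring (0.17) and centring on the genes' median (0.10), where adding 0.11 to every ratio moved it, and Ly6e (-0.022), Cox5b (-0.032) and Cxcr5 (-0.39) turned with median centring. Apart from that added constant, the cause of these turns was not tested. Prior degrees of freedom were infinite in the main fit, 7.95 with the Feature Extraction ratios, 3.23 with separate channels and 2.38 without the filter. Separate channels called 0 genes with the same 9949 tested, so a larger number of genes cannot account for that loss. Without the filter, both the number of genes and the prior differed. Their parts in the calls were not tested separately. List tests were not run against a 1.2-fold change or on 1 array. No paired analysis was possible beyond the test given because that test is itself paired, with both groups of a replicate in 1 ratio per array. Separate channels were fitted with an intraspot correlation of -0.10. Signal over background limits the dim genes: 181 of 591 lower genes were not well above background in deficient cells.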

Other observations

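Tests chosen after the result was seen were the second macrophage list, the comparison of macrophage with B-cell markers, the random lists, the correlation of the arrays across T-cell receptor genes, the split by intensity and the centring of arrays. The correlation against random lists took the place of 2 earlier tests of the same members, a chi-square of their spread and a permutation of their pairing, which both came out against dilution alone but took no account of dye effects shared by the arrays.

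Further macrophage genes outside every fixed list were measured, from a list written for this test. Of 20 genes, 11 were called higher, among them Sirpa (2.83 ± 0.44, SD, n = 2), Creg1 (2.57 ± 0.09), the lysosomal protease Lgmn (2.43 ± 0.84), Aif1 (2.24 ± 0.06) and transferrin Trf (2.08 ± 0.39). Others lay near 0, such as Grn (-0.21 ± 0.33) and Npc2 (0.18 ± 0.37). Spic, a transcription factor of red pulp macrophages in the spleen, stood at 3.01 ± 0.07 and was chosen after its value was seen. Bcl11a, the paralogue of Bcl11b, had a log2 ratio of 1.15 ± 0.67 by its tested probe and did not pass (limma adjusted p = 0.0592). Other probes for it, too dim to be tested, gave opposite signs on replicates 1 and 2 (-0.52 and 1.43, and -0.64 and 0.60). Bcl11a too was chosen after its value was seen.

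Macrophage genes were higher in the deficient samples, at a median of 2.35 on the log2 scale. Other genes of like intensity did not share the rise: 0% of 10000 random lists matched on intensity had a median as high, and their 97.5th percentile was 0.28. Loess had already centred the ratios at each intensity, so such lists were bound to lie near 0. The test therefore gives no verdict on an intensity-dependent dye effect. Macrophage markers rose more than B-cell markers: 17 macrophage markers averaged 2.49 ± 0.73 (SD) and 13 B-cell markers 1.58 ± 0.54. The difference was 0.92 (permutation p = 8.7e-04 over 100000 resamples, two-sided, across genes, which are not independent replicates). This cannot decide whether a lower share of CD8+ cells raised every other cell type alike. Equal rises would follow only if no other cells expressed the markers and unremoved background lowered their ratios alike, and neither was tested. More macrophages in the deficient preparations remain a candidate explanation. Of the second macrophage list, 80% (16 of 20 genes) lay above 0 on both arrays, exactly the bound, which was set after the macrophage rise was seen. That result does not separate this explanation from those that follow. Negative selection with a purity above 90% would leave room for a minority of such cells. A dye effect particular to these genes cannot be told apart from genotype, because 0 arrays had the dyes swapped, and expression of these genes by deficient T cells themselves was not tested.

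T-cell receptor and CD8 signalling genes were lower, at a median of -0.88. Among random lists matched on intensity, 0% had a median as low, and their 2.5th percentile was -0.39. Here too loess had already centred the ratios at each intensity, so the test gives no verdict on an intensity-dependent dye effect. Dilution of T-cell RNA by other cells, alike for every T-cell gene, cannot be told apart from other causes: the 29 members spread by an SD of 0.80, but their differences recurred between the arrays no more than those of other genes (r = 0.591 across members, and 69.8% of random lists matched on intensity had an r as high), and both arrays share the dye orientation. At a purity of 90%, the stated lower limit, in deficient samples and equal RNA per cell, such dilution would lower T-cell genes by 0.15 on the log2 scale. That value takes wild-type samples as free of other cells. Yet C1qc, Adgre1 and Csf1r were well above background in the wild-type channel on both arrays. Neither the purity of each sample nor the RNA per cell was available here. Dye effects particular to a probe and an effect of Bcl11b on these genes also remain open.

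More genes were called lower than higher (61.9% of calls). Lower genes made up 39.5% of 511 calls among the brighter genes, split at the median intensity, and 87.8% of 443 calls among the dimmer ones; this restates that lower calls were dimmer, so dim genes lying below 0 cannot be told apart as a cause. A shift of replicate 1 below 0 cannot be told apart from other causes by the test run, as centring each array left 51.2%, between the bounds set for it. A filter that keeps dim genes through the wild-type channel cannot be told apart either: requiring both channels above background gave 28.7%, but that filter itself removed 83.6% of the lower calls and 12.7% of the higher ones. A true excess of lowered genes at low expression was not tested.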
